A study of Mus musculus with 6 samples.

How the data were processed

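ESRRB ChIP-seq was measured in E14 mouse embryonic stem cells in 2iL and at 48 h and 96 h after 2iL withdrawal, with 1 antibody library and 1 input library (chromatin before the antibody step) per condition. Chromatin was fixed with 1% formaldehyde, and 10 ng of DNA went into each library, per the labels. The processed data used here were 3 peak lists, 1 for each antibody library. The 3 input libraries were not used here, and whether the authors used them as controls is not given in the sources used here.

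Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20.0.422, the tools BWA, SAMtools, Picard and MACS2 were used, and the genome build was mm10. The role of each tool, the versions of the other 4, the mapping filters and the calling threshold are not given in the sources used here. Each line of a deposited list is a summit in an interval, and 40.4% of intervals in 2iL, 33.5% at 48 h and 31.4% at 96 h hold more than 1 summit. The authors' score is capped at 1000 and is otherwise, to within 3 units, a fixed multiple of a number inside each peak name. From the values, that number is the −log10 of a rate of at most 0.05, and which rate it is is not given in the sources used here. The fold enrichment that the authors deposited is a ratio of the reads at the summit to the local background, with a pseudocount of 1 on both. The deposited p-value of each summit is given as −log10 of a Poisson p against the local background. The deposited q-value is given as −log10 of the p adjusted within the library, and the deposited summit offset is in base pairs from the start of the interval.

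The unit of all comparisons was the region, a unique interval, with the fold of its highest summit. The lists held 22182, 16348 and 10011 summits in 13767, 10970 and 7018 regions, with median widths of 993, 979 and 878 bp. The files give no read totals. Fold and p together gave the reads at each summit, which were whole numbers for 100% of summits in each library within 0.05 of a step, against 10.7% by chance. The lowest background they gave, a floor set by the library's depth, was 5.04 reads in 2iL, 8.09 at 48 h and 5.84 at 96 h, and the median number of reads at a summit was 39, 55 and 38. That floor also depends on the fragment length, so it was divided by the shortest region (224, 241 and 238 bp) as well, which gave 1.49 times the 2iL value at 48 h and 1.09 times at 96 h. Folds were ranked within a library and not tested between libraries.

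Regions were called shared when they overlapped by at least 1 bp, computed with bedtools 2.31.1 and checked with independent code, which gave the same counts. Chance overlap came from 100 shuffles of positions within chromosomes. Regions were ranked by fold and split into 5 equal groups. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. With 1 library per condition no test between conditions was possible, and no p-value was computed.

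Genes came from the RefSeq annotation of the same assembly, which was used as gene start, end and type. Strand and exons are not given in the sources used here, so distances were taken to the gene span and gene ends replaced transcription start sites. A gene end is the start or the end of the span, whichever is nearer. Exons and introns were not told apart. A summit within 50 kb of a gene span was counted as near the gene, and place was given relative to protein-coding genes. The 9 gene lists (naive, core and formative pluripotency, neural, mesoderm and endoderm, trophoblast, energy metabolism, 2iL signalling targets and tissue-specific control genes) held 142 genes, 6 of them in 2 lists, and all matched the annotation. Members near a region were compared with 10000 random gene lists matched on gene density within 100 kb, and the share of 2iL regions near a list that was called later with 10000 random sets of 2iL regions matched on the fifth of fold they fell in. Sets matched in this way are called equally strong, and they were not matched on p, on reads or on width. Percentiles outside 2.5 to 97.5 are described as beyond the central 95%. There were 18 shares and 27 counts of this kind, and the percentiles were not corrected for that number.

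Named genes were, by rule, the members of each list near a region that differed between libraries, up to 12 per list by the highest fold of their 2iL regions, and members with no region in any library. Named regions were the 10 of highest fold in each library, the 10 strongest 2iL regions called at neither later time, and the 10 strongest at 48 h and at 96 h not called in 2iL, each with its nearest protein-coding gene. Genes outside the rule are given as chosen after their values were seen. Some genes that the rule names are not reported here.

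The lists, the rule, the comparisons and most alternatives were set before the data were examined. The alternatives were a q of 1e-05 or less, lists of equal length by fold, overlap of at least 50% of both regions, summits within 100 bp, ranking by p, regions moved by 20 to 200 kb in place of shuffling, 2.5 kb in place of 1 kb around gene ends, a 10 kb window and the nearest gene only. Those added after the data were seen were summits as the unit, the ends of all annotated genes, random gene lists matched on gene length as well, matching on 50 groups of fold, and counts of genes with more or fewer regions than in 2iL or with a region not called there. The shares of the strongest 5% of regions missing from another list, and the shares called at 96 h split by the call at 48 h or in 2iL, were also computed after the data were seen. The planned search for the ESRRB motif at summits was not run, since it needs the genome sequence, which was not used here.

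The code was tested on simulated data. In a list made from the 2iL list with 6949 regions kept, 6949 were found, and 0.807% of the regions that were not kept overlapped by chance. Among 400 simulated lists of 44 regions with no difference, 4.75% lay outside the central 95%, and with 30 percentage points added 99.8% did. These simulated lists drew single regions and not neighbours near a few genes. The rates need not hold for the real gene lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.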

Results

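ESRRB is a nuclear receptor that binds DNA as part of the naive pluripotency network, and its binding was mapped by ChIP-seq (sequencing of chromatin pulled down with an antibody) in E14 mouse embryonic stem cells. The cells were kept in 2iL, which holds them in the naive state with 3 µM CHIR99021 (an inhibitor of the kinase GSK3), 1 µM PD0325901 (an inhibitor of the kinase MEK) and the cytokine LIF, or were sampled 48 h and 96 h after 2iL was withdrawn. Each condition had 1 ESRRB library and no replicate, so values below describe these libraries and carry counting intervals only. The lists held 13767 ESRRB regions in 2iL, 10970 at 48 h and 7018 at 96 h, which covered 15.2, 12.1 and 6.85 Mb of the mm10 genome. The median fold enrichment over local background was 5.88 in 2iL, 4.98 at 48 h and 4.82 at 96 h. Total read counts were not used here, and the background level behind the folds was 1.60 times that of 2iL at 48 h and 1.16 times at 96 h. Folds set side by side below are each over their own library's background and show no tested change in binding.

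The first comparison asks which ESRRB regions of naive cells were still called after 2iL withdrawal, and which were called only then. The strongest ESRRB regions were called in all 3 libraries: a region inside Pld1, a phospholipase gene (chromosome 3, 28113227 to 28115445), had a fold of 48.2 in 2iL, 42.8 at 48 h and 47.6 at 96 h. A region inside Nrip1, which encodes a nuclear receptor corepressor (chromosome 16, 76319393 to 76322574), had folds of 39.4, 32.8 and 36.2. Of the 13767 regions of 2iL, 6981 (50.7%, 95% interval 49.9 to 51.5) overlapped a 48 h region and 4822 (35.0%, 34.2 to 35.8) overlapped a 96 h region. In the other direction, 63.5% of 48 h regions and 69.5% of 96 h regions (95% interval 68.4 to 70.6) were also called in 2iL. Positions shuffled within chromosomes gave an overlap of 0.987% for 2iL regions in the 48 h list and 0.606% in the 96 h list.

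When overlapping regions of the 3 lists were merged, 4260 of 18634 merged regions (22.9%) were called in every library and 6277 (33.7%) in 2iL alone. Another 2888 were called at 48 h alone, 1001 at 96 h alone and 1103 at both later times but not in 2iL. A 2iL region called at 48 h was called at 96 h in 61.8% of cases (95% interval 60.6 to 62.9), and a 2iL region not called at 48 h in 7.50% (6.89 to 8.15). Of the 4002 regions of 48 h that were not called in 2iL, 27.8% were called at 96 h. Of the 48 h regions that were called in 2iL 61.7% were, and the groups were not matched on strength. The background floor was 8.09 reads at 48 h and 5.84 at 96 h, so lower depth at 96 h may have left weak 48 h regions uncalled. A region that was not called may still have held ESRRB below the calling threshold. When each list was shortened to the 7018 strongest regions, 47.8% of 2iL regions were in the 96 h list and 48.7% of 96 h regions in the 2iL list.

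**Figure D1:**
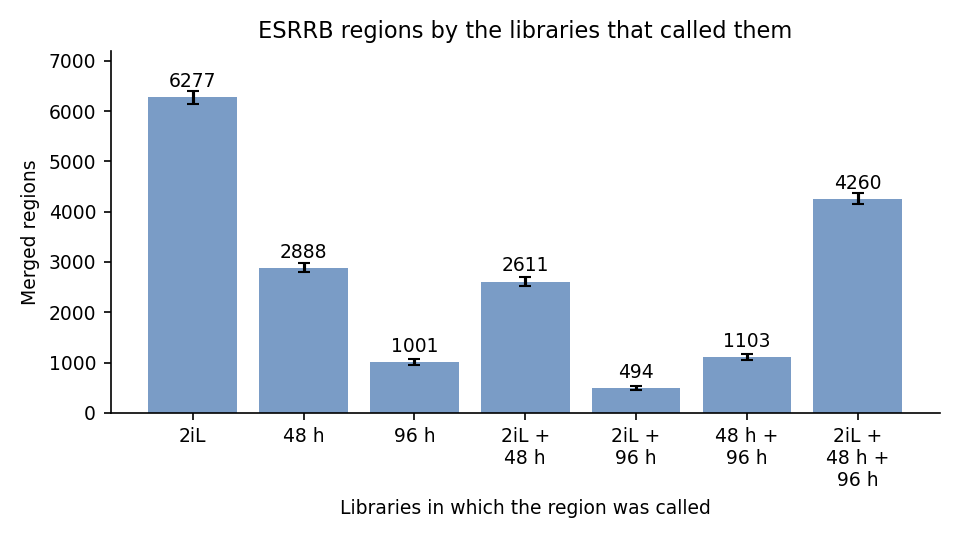
Number of merged ESRRB regions (vertical axis) by the libraries that called them (horizontal axis), with exact 95% binomial intervals that cover counting error only. Regions called in 2iL alone (6277) outnumbered those called in all 3 libraries (4260).

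Strong 2iL regions were called later more often than weak ones. In the weakest 20% of 2iL regions by fold enrichment, 30.4% were called at 48 h and 17.6% at 96 h, and in the strongest 20% 77.5% and 62.1%. The median fold in 2iL was 7.60 for the 4313 regions called at both later times and 5.19 for the 6277 called at neither. Among the 2753 regions of the strongest 20%, with a fold of at least 8.71, 553 (20.1%, 95% interval 18.6 to 21.6) were called at neither later time. Later regions that were not called in 2iL were mostly weak. The median fold of 48 h regions was 4.25 when not called in 2iL and 5.69 when called there. At 96 h it was 4.09 and 5.36. The background floor at 48 h was 1.60 times that of 2iL, so greater depth may have let weak regions be called there.

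**Figure D2:**
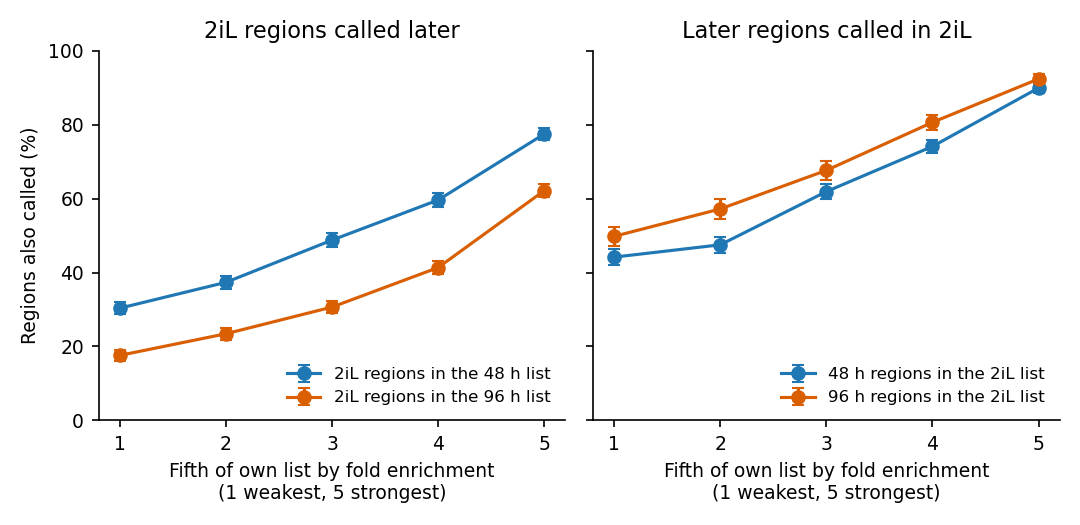
Percent of regions also called in another library (vertical axis) by the fifth of the region's own list ranked by fold enrichment (horizontal axis), for 2iL regions in the later lists (left) and later regions in the 2iL list (right), with exact 95% binomial intervals. Shares are higher in the strongest 20% of each list than in the weakest, as for 2iL regions at 96 h, with 17.6% and 62.1%.

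The 10 strongest regions of each library were called in all 3 libraries, and regions nearest Pld1, Myrip, Pdgfa and Nrip1 were among the 10 strongest in each. The region inside Myrip, a gene for a myosin-linked trafficking protein (chromosome 9, 120336225 to 120337473), had a fold of 46.3 in 2iL, 38.5 at 48 h and 32.9 at 96 h. The region 1.04 kb from Pdgfa, a growth factor gene (chromosome 5, 138974141 to 138975974), had folds of 40.7, 33.9 and 38.9. The other strongest 2iL regions lay nearest Asmt, Msrb2, Pcdh9, Tbc1d1, Ralgapa2 and Atg14, with folds of 33.3 to 39.1. The other strongest regions at 48 h lay nearest Klf4, Hey2, Mbip, Cacna2d3, Fam240b and Tbc1d1. At 96 h the highest fold was 60.9, in a region inside the calpain gene Capn2 (chromosome 1, 182499834 to 182501789), and the others lay nearest Tsr2, Mbip, Ccdc138, Gm9733 and Klf4.

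Naive pluripotency genes lay near many 2iL regions, and 14 of the 20 listed had fewer regions within 50 kb at 48 h and 16 at 96 h, with none having more. Random genes with as many 2iL regions gave medians of 14 and 17 with fewer, so these counts lay inside the central 95%, at the 43.1 and 21 percentiles. A region lay within 50 kb of 19 of the 20 genes in 2iL and of 17 at each later time, beyond the central 95% of 10000 random gene lists in each library. Of the 12 regions at Esrrb itself, all inside the gene, 4 were called at both later times and 8 at neither. The strongest of them (chromosome 12, 86501273 to 86502844) had a fold of 17.9 in 2iL, 17.8 at 48 h and 19.9 at 96 h. The region beside it (86502976 to 86505046) had folds of 17.0, 4.10 and 4.07. Nanog, which encodes a homeobox factor of the naive network, had 6 regions in 2iL, 3 at 48 h and 4 at 96 h, and its strongest region (chromosome 6, 122689727 to 122690988, fold 10.5) was called at 96 h but not at 48 h. The strongest regions near Klf2 (fold 15.6), Nr0b1 (14.96), Tfcp2l1 (12.7), Jam2 (13.2), Socs3 (15.4), Zfp42 (10.9), Klf5 (10.4), Fgf4 (10.4) and Dppa5a (10.1) were called at both later times. The strongest region near Tbx3 (fold 13.1) was called at 96 h only, and Tcl1 had no region in any library.

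Among naive genes chosen after their values were seen, Gbx2, a homeobox gene, had 4 regions in 2iL and none at either later time, with a highest fold of 7.33 (chromosome 1, 89934735 to 89937691). Both 2iL regions within 50 kb of Klf4 were called at neither later time. At 96 h a region 49628 bp from Klf4 had a fold of 9.23 and overlapped regions of 2iL and 48 h. A region 51.5 kb from Klf4 (chromosome 4, 55474891 to 55478073) was called in all 3 libraries. Its fold was 33.8 at 48 h and 30.3 at 96 h. Dppa3 had 2, 1 and 0 regions, and Nr5a2 had 5, 1 and 2. Of the 95 regions of 2iL near naive genes, 50 (52.6%, 95% interval 42.1 to 63.0) were called at 48 h and 41 (43.2%, 33.0 to 53.7) at 96 h. Those shares lay at the 59.5 and 94.1 percentiles of 10000 random sets of equally strong 2iL regions, and within 10 kb of the genes at the 97.6 and 99.6 percentiles.

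**Figure D3:**
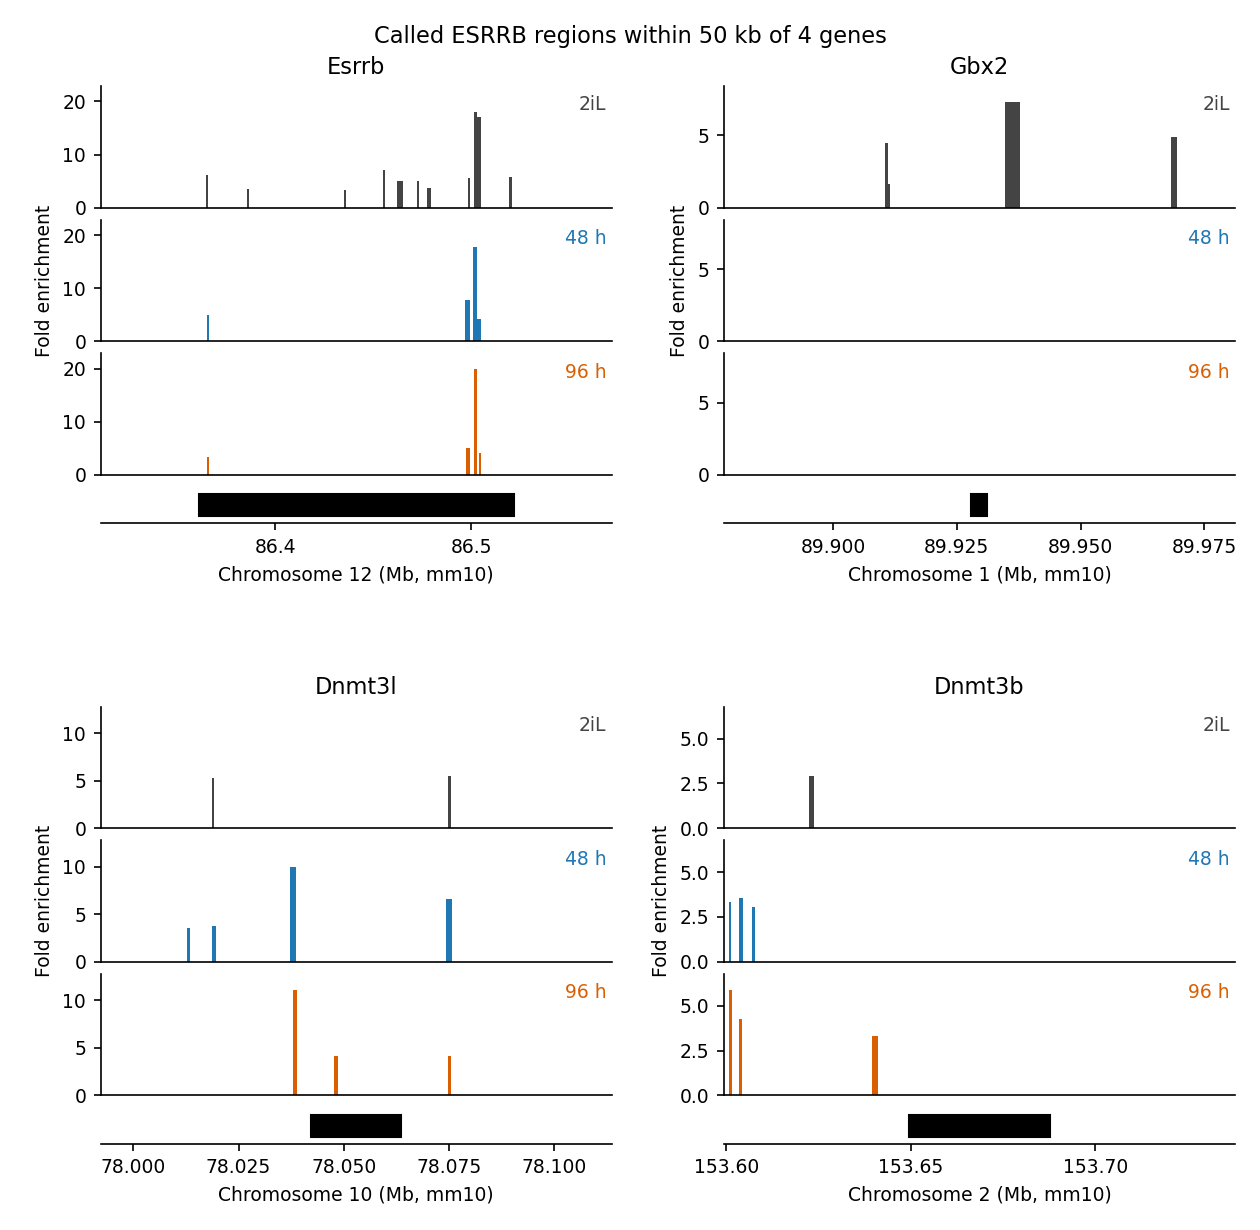
Called ESRRB regions within 50 kb of Esrrb, Gbx2, Dnmt3l and Dnmt3b in the 3 libraries, with mm10 position on the horizontal axis, each region's fold enrichment over its own library's background on the vertical axis, and the gene as a black bar; narrow regions are drawn at a minimum width. Gbx2 shows 4 regions in 2iL and none later, while Dnmt3b shows 3 regions at each later time that were not called in 2iL.

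Regions near core pluripotency genes were called at 48 h more often than equally strong 2iL regions. A region lay within 50 kb of 12 of the 13 core genes in 2iL and at 48 h and of 10 at 96 h, beyond the central 95% of random gene lists in each library. Of their 36 regions in 2iL, 28 (77.8%, 95% interval 60.8 to 89.9) were called at 48 h and 19 (52.8%, 35.5 to 69.6) at 96 h, at the 99.97 and 98.8 percentiles of the random sets. All 4 regions of 2iL near Sall4, a zinc finger factor gene, were called at 48 h and 3 of them at both times. Pou5f1, which encodes OCT4, had 9 regions in 2iL, 5 at 48 h and 2 at 96 h, and its strongest (chromosome 17, 35502075 to 35503148, fold 8.69) was called at neither later time. Sox2 had 4, 3 and 2 regions, and its highest fold was 8.86 in 2iL, 11.3 at 48 h and 13.0 at 96 h. Utf1 kept all 3 regions at 48 h, Foxd3 both of its regions, and Zfp281 had 4, 3 and 3 regions. Dppa4 and Dppa2, which are neighbours, had 2 regions in 2iL, 2 at 48 h and none at 96 h, and the Lin28a region of 2iL (fold 8.93) was called at neither later time. With an overlap of at least 50% of both regions, the core share at 48 h lay at the 92.4 percentile, and with lists of equal length at the 88.8 percentile. The core share at 96 h came inside the central 95% in those settings (91.3 and 96.6 percentiles), with a 10 kb window (96.4) and against random gene lists drawn as whole genes (96.8).

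Formative pluripotency genes, which cells switch on as they leave the naive state, kept 30 of 44 regions of 2iL at 48 h (68.2%, 95% interval 52.4 to 81.4) and 22 (50%, 34.6 to 65.4) at 96 h. Those shares lay at the 98.9 and 97.4 percentiles of equally strong 2iL regions, the second inside the central 95% of the random sets. A region lay within 50 kb of 16 of the 20 formative genes in 2iL and at 48 h and of 14 at 96 h, beyond the central 95% of random gene lists, except in 2iL with lists of equal length (93.99 percentile). The strongest regions near Otx2 (fold 14.9), Lef1 (21.9), Tcf15 (18.9), Grhl2 (6.34) and Tead2 (10.9) were called at both later times. The strongest near Pou3f1 (13.4), Etv5 (17.0), Tcf7l1 (18.4) and the neighbours Zic2 and Zic5 (5.44) were called at 48 h only, and that near Sox4 (7.28) at neither. Dnmt3l, which encodes a cofactor of DNA methylation, had 2 regions at each later time that were not called in 2iL, and 1 of them, 3980 bp from the gene (chromosome 10, 78037918 to 78038869), had a fold of 11.1 at 96 h. Sox3, Sall2 and Lin28b had no region in any library. The formative share at 48 h lay at the 79.6 percentile with a 10 kb window and at the 85.5 percentile with an overlap of at least 50% of both regions.

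Other formative genes were chosen after their values were seen. Dnmt3b, a DNA methyltransferase gene, had 1 region in 2iL, called at neither later time, and 3 regions at each later time that were not called in 2iL, at folds of up to 3.53 at 48 h and 5.89 at 96 h. At 48 h a weak region inside Fgf5 (chromosome 5, 98255711 to 98256154, fold 2.87) was called, and it was not called in 2iL or at 96 h. The region near Cldn6 was called only in 2iL.

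Among lineage genes, a 2iL region lay within 50 kb of 7 of 15 neural genes, 8 of 15 mesoderm and endoderm genes and 9 of 13 trophoblast genes, at the 36.1, 55.3 and 88.3 percentiles of random gene lists. At 96 h the counts were 4, 5 and 4, at the 24.3, 44.4 and 36.1 percentiles. At 48 h they were 6, 7 and 9, at the 32.8, 51.5 and 94.1 percentiles, and the trophoblast count lay at the 99.8 percentile when regions were counted for the nearest gene only and at the 98.4 when random lists were matched on gene length. Wnt3, a signal of mesoderm formation, had 2 regions in 2iL (highest fold 9.86) and Pax3 had 2 (6.91), none of which was called later. The regions of 2iL near Bmp4 (highest fold 11.2), Satb1 (7.13), Sox21 (4.2) and Dll1 (9.33) were not called at 96 h. Tfap2c, a gene of naive cells and trophoblast, had 9, 8 and 8 regions, of which 6 regions of 2iL were called at both later times, the strongest at a fold of 21.98. No region was called in any library near 7 neural genes (Neurog1, Neurog2, Zic1, Hes5 and Map2 among them), 4 mesoderm and endoderm genes (Mixl1, Gsc, Foxa2 and Lhx1) or 3 trophoblast genes (Elf5, Krt18 and Krt8).

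The remaining named lineage genes differed between libraries in other ways. Tubb3 had 3, 2 and 1 regions, Msi1 7, 3 and 4, and Nes 1, 2 and 2, while Sox1 had 1 region in each library, of which that of 2iL was called at neither later time, and Olig3 had 1 in 2iL alone. The mesoderm gene T had 3, 0 and 2 regions, Eomes 2, 1 and 2, Nodal 2, 2 and 1, Sox17 and Cxcr4 1, 1 and 0, and Gata4 1 in 2iL alone. In the trophoblast list, Cdx2 had 2, 2 and 1, Hand1 3, 2 and 0, Id2 3, 3 and 2, Tead4 3, 2 and 2, and Ascl2 1 in 2iL alone. Of the 2iL regions near the 3 lists, 43.8%, 50% and 64.3% were called at 48 h and 25%, 35.7% and 39.3% at 96 h, all inside the central 95% of equally strong regions.

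Energy metabolism genes, a class bound by estrogen-related receptors, lay near ESRRB regions in each library. Regions lay within 50 kb of 18 of 20 genes in 2iL, 19 at 48 h and 17 at 96 h, beyond the central 95% of random gene lists. The strongest 2iL regions near Atp5a1 (fold 19.0), Sdha (14.9), Esrra (13.2), Acadm (10.5), Cox5a (9.50), Ndufs1 (8.61), Slc25a4 (8.03), Sdhb (6.25) and Uqcrc2 (6.15) were called at both later times, and those near Atp5b (10.0) and Cs (6.22) at neither. Ppargc1a, which encodes a coactivator of these receptors, had no region in any library. Of their 39 regions in 2iL, 24 (61.5%) were called at 48 h and 18 (46.2%) at 96 h, at the 88.9 and 89.4 percentiles. Within 10 kb of the genes they lay at the 98.7 and 98.4 percentiles, and at 50 kb with random sets matched on place relative to gene ends as well at the 66.3 and 51.7.

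Targets of the signals that 2iL sets had regions near 15 of 16 genes in 2iL, 14 at 48 h and 12 at 96 h, beyond the central 95% of random lists. Axin2, a target of WNT signalling, had 4, 2 and 0 regions, and Dusp6, a target of the MEK pathway, had 3, 1 and 0. Spry2 had 7, 6 and 5 regions, of which the strongest (fold 15.4) was called at both later times. Spry4 had 2, 5 and 3, with 3 regions at 48 h that were not called in 2iL, and Lef1 had 2, 5 and 2. Cdx1 had 5, 3 and 3, Fos 5, 2 and 3, and Tcf7 1, 2 and 0, and Nkd1 had none in any library. Of the 55 regions of 2iL near these genes, 34 (61.8%) were called at 48 h and 24 (43.6%) at 96 h, at the 92.1 and 84.5 percentiles.

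A region lay within 50 kb of 8 of 16 control genes of other tissues in 2iL and of 5 at each later time, at the 29.5, 6.51 and 22.6 percentiles of random lists, inside the central 95%. Alb, Ins1, Ins2, Hbb-bt, Hba-a1, Cd3e and Csn2 had no region in any library. Myl1 had 3, 3 and 1 regions with a highest 2iL fold of 20.5, Apoa2 had 3, 4 and 5, Mb 4, 0 and 1, Myh6 1, 2 and 1, Ckm 1, 1 and 0, Prl 2 in 2iL alone and Gh 1 in 2iL alone. Of the 17 regions of 2iL near control genes, 3 (17.6%, 95% interval 3.80 to 43.4) were called at 48 h, at the 0.175 percentile, and 6 (35.3%) at 96 h, at the 54.7 percentile. The low share at 48 h lay at the 14.4 percentile with a 10 kb window and at the 18.5 percentile with lists of equal length.

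**Figure D4:**
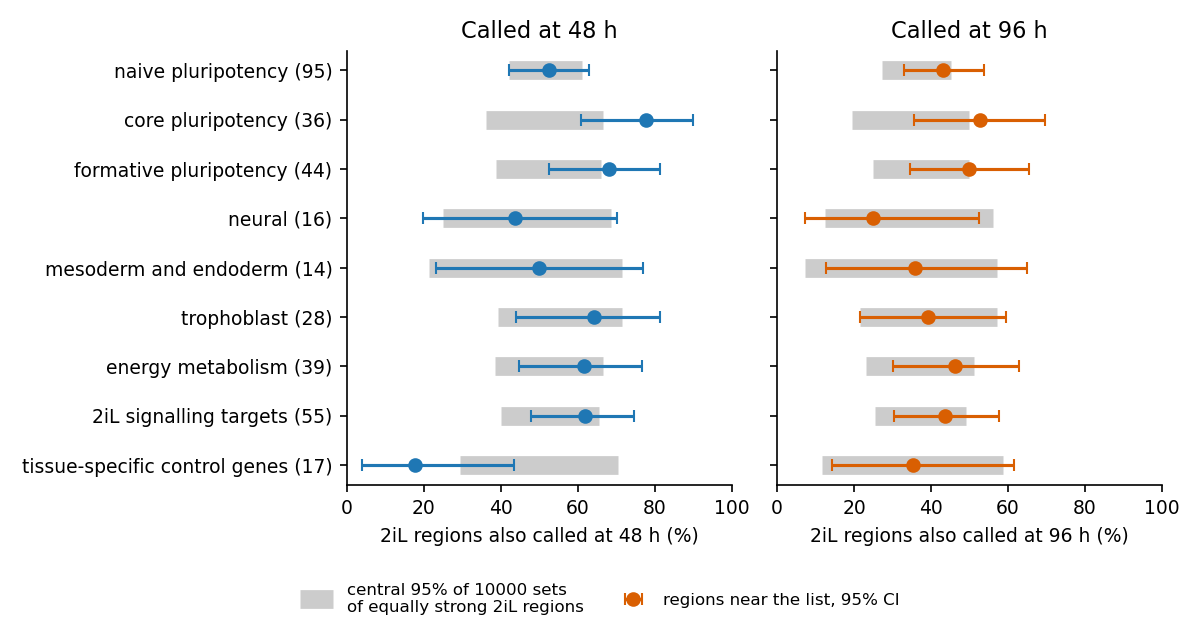
Percent of 2iL regions within 50 kb of each gene list (number of regions in brackets) that were called at 48 h (left) and 96 h (right), as points with exact 95% binomial intervals, over the central 95% of 10000 sets of equally strong 2iL regions in grey. The core list (77.8%) and the formative list (68.2%) lie above the grey band at 48 h and the control list (17.6%) below it.

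Summits lay within 1 kb of either end of a protein-coding gene in 10.8% of regions in 2iL (95% interval 10.3 to 11.4). The share was 10.4% at 48 h (9.85 to 11.0) and 13.1% at 96 h (12.3 to 13.9). Shuffled positions gave 3.10%, 2.92% and 3.43%. Elsewhere inside a gene lay 41.7%, 42.3% and 39.3%, and more than 50 kb from any gene lay 17.3%, 17.3% and 16.7%, against 34.6%, 34.5% and 34.6% when shuffled. With lists cut to the 7018 strongest regions by fold, the gene-end share was 8.15% in 2iL and 8.06% at 48 h. The 13.1% at 96 h is that of its whole list, weak regions included, so these shares do not compare like parts of the lists. Of the 2iL regions called at both later times, 13.2% (95% interval 12.2 to 14.3) lay within 1 kb of a gene end, against 9.32% (8.61 to 10.1) of those called at neither. The share was 8.32% for 48 h regions not called in 2iL and 11.6% for such regions at 96 h.

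The strongest 2iL regions called at neither later time lay nearest Bach1, which encodes a repressor that binds haem, at 7.70 kb (chromosome 16, 87690635 to 87692027, fold 28.0), nearest Ffar2, a fatty acid receptor gene (chromosome 7, 30827297 to 30829658, fold 24.1), and nearest Fam189a2 (chromosome 19, 23968020 to 23969936, fold 22.6). The others lay nearest Pdcd6ip, Lyzl4, Slc39a11, Bcar3, Opcml, Cd83 and Slc25a13, with folds of 19.7 to 22.2.

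The strongest 48 h regions not called in 2iL lay nearest Map1b, a microtubule protein gene, at 40.3 kb (chromosome 13, 99556424 to 99557515, fold 14.3), nearest Gap43 (fold 14.3), inside the prostaglandin receptor gene Ptger3 (chromosome 3, 157607149 to 157608688, fold 14.2) and inside the growth factor receptor gene Fgfr2 (chromosome 7, 130251484 to 130252812, fold 13.3). The others lay nearest Rfx3, Fgf1, Oaz2, Etl4, Cmip and Ubl3, and all 10 were also called at 96 h. At 96 h the strongest regions not called in 2iL lay inside Kndc1 (chromosome 7, 139936242 to 139938202, fold 14.3) and inside Cubn, a receptor gene (chromosome 2, 13338453 to 13339669, fold 14.03). The others lay nearest Kcnh1, Elfn1, Pde7b, Calm2, Igsf3, Nuak1, Ccsap and Aire, and 9 of the 10, all but that near Nuak1, were also called at 48 h.

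Most strong regions of 48 h and 96 h were called at both times. Of the strongest 5% of regions, 9 of 548 at 48 h (1.64%, 95% interval 0.754 to 3.09) were not called at 96 h, and none of 350 at 96 h was missing from the 48 h list. Of the strongest 5% in 2iL, 85 of 688 (12.4%, 9.99 to 15.05) were not called at 48 h and 160 (23.3%) were not called at 96 h. In the reverse direction, 14 of the 548 at 48 h (2.55%, 1.40 to 4.25) were not called in 2iL, an interval that overlaps that of the 9 not called at 96 h. In all, 78.3% of 96 h regions (95% interval 77.3 to 79.3) were called at 48 h, and 49.3% of 48 h regions were called at 96 h. Lower depth at 96 h, with a background floor of 5.84 reads against 8.09 at 48 h, may account for part of that difference.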

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

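The alternatives were planned except summits as the unit, the ends of all annotated genes, random gene lists matched on gene length and matching on 50 groups of fold, which were chosen after the data were seen. No paired analysis was possible because each condition has 1 library, and the motif search with its 4 alternatives was not run. Of 253 shares and counts recomputed, 190 stayed within the main value's interval or within 1.5 times the main count, 50 moved outside the interval and 13 counts were lower by more than 1.5 times. Of 108 percentiles of shares kept near gene lists, 92 stayed on their side of the central 95%, 9 moved inside it and 7 moved outside it. Of 135 percentiles of members near a region, 132 stayed on their side, and 3 did not. The formative list in 2iL moved inside, to the 93.99 percentile, with lists of equal length, and the trophoblast list at 48 h moved outside, to the 99.8 with the nearest gene only and to the 98.4 with random lists matched on gene length as well. Of 1695 values of single named genes, 281 moved, and no value reversed. The 6 chance overlaps moved when regions were shifted by 20 to 200 kb, to between 1.14% and 2.30%. Read depth, known here only as a relative background, limits which weak regions could be called, and 1 library per condition limits every comparison. Where no reason is given, the cause was not tested.

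With lists of equal length, which removes the weakest regions of 2iL and 48 h by construction, 54.8% of 2iL regions were in the 48 h list and 47.8% in the 96 h list. In the same setting 54.8% of 48 h regions were in the 2iL list and 61.7% in the 96 h list, and 48.7% of 96 h regions were in the 2iL list and 63.1% in the 48 h list. The strongest and weakest 20% of 2iL regions differed by 39.9 percentage points at 48 h and 37.0 at 96 h, against 47.1 and 44.6 in the main setting. Summits within 1 kb of a gene end made up 8.15% in 2iL and 8.06% at 48 h. Regions of 2iL lay near 4 neural and 5 mesoderm and endoderm genes. The share of 2iL regions called at 96 h was 64.7% near naive, 66.7% near formative, 73.7% near energy metabolism and 66.7% near signalling genes. The core list lay at the 88.8 percentile at 48 h and the 96.6 at 96 h, the control list at the 18.5 at 48 h and the naive list at the 99.1 at 96 h.

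With an overlap of at least 50% of both regions, 44.1% of 2iL regions were called at 48 h and 29.0% at 96 h. Of 48 h regions 55.3% were called in 2iL and 43.2% at 96 h, and of 96 h regions 56.8% in 2iL and 67.5% at 48 h. The strongest and weakest 20% differed by 43.7 points at 48 h and 37.3 at 96 h. At 48 h 55.6% of core and 52.3% of formative regions were kept, at the 92.4 and 85.5 percentiles, and at 96 h 32.6% of naive regions, with the core list at the 91.3 percentile. With summits within 100 bp, 48.1% and 32.8% of 2iL regions were called at 48 h and 96 h, 60.3% and 46.8% of 48 h regions in 2iL and at 96 h, and 64.6% and 73.8% of 96 h regions in 2iL and at 48 h. The formative list at 96 h then lay at the 98.9 percentile.

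With summits as the unit, those shares were 53.6% and 37.8% for 2iL, 65.7% and 52.8% for 48 h, and 71.5% and 80.2% for 96 h. With a q of 1e-05 or less, 71.9% of 96 h regions were called in 2iL and 81.1% at 48 h, and the formative list at 96 h lay at the 98.4 percentile. Ranked by p, the strongest and weakest 20% differed by 56.9 points at 48 h and 54.7 at 96 h.

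Within 10 kb, regions lay near 3 neural genes in 2iL, 3 at 48 h and 1 at 96 h, near 5 mesoderm and endoderm genes in 2iL and 1 at 96 h, and near 2 trophoblast genes at 96 h, since the window takes in fewer regions. The share kept at 48 h was 67.3% for naive and 93.3% for core genes, and at 96 h 55.8% for naive genes. At 48 h the naive list lay at the 97.6 percentile, formative at the 79.6, energy metabolism at the 98.7 and control at the 14.4. At 96 h the naive list lay at the 99.6, core at the 96.4 and energy metabolism at the 98.4. Counted for the nearest gene only, regions lay near 5 control genes in 2iL, 3 at 48 h and 3 at 96 h, and at 96 h near 2 neural and 2 mesoderm and endoderm genes.

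Summits within 2.5 kb of a gene end made up 17.7% in 2iL, 17.5% at 48 h and 20.3% at 96 h, and with the ends of all annotated genes 16.1%, 15.8% and 18.8% lay within 1 kb, since both settings take in more sequence.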

Other observations

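The counts of genes with more or fewer regions, the levels at shared regions, the shares of later regions near gene lists called in 2iL, the leaving out of single genes, the 4 tests of depth and of a uniform loss and the chromosome 8 test at 48 h were chosen after the results were seen. At 96 h, 7 of the 20 formative genes had more regions than in 2iL and 6 had fewer, whereas random genes with as many 2iL regions gave a median of 1 with more (central 95% 0 to 4) and 12 with fewer (9 to 15). Part of that count did not come from added places: Otx2, Dnmt3a and Tcf15 had more regions at 96 h, but each of these overlapped a 2iL region. A region at 96 h that was not called in 2iL lay near 7 formative genes (Dnmt3b, Dnmt3l, Grhl2, Tead2, Lef1, Pou3f1 and Tcf7l1), at the 94.9 percentile, inside the central 95%. Grhl2, an epithelial regulator, had 2 regions in 2iL, 2 at 48 h and 5 at 96 h, and Tead2, a partner of YAP, had 1, 2 and 4, with 3 regions at 96 h near each that were not called in 2iL. At 48 h, 7 formative genes also had more regions (99.25 percentile). Of the 13 core genes, 5 had more regions at 48 h (99.05 percentile) and 4 fewer (1.56), and 6 had fewer at 96 h (0.47). Of the 20 naive genes, none had more regions at either later time, at the 6.14 percentile at 48 h and the 24.9 at 96 h, while a region at 48 h that was not called in 2iL lay near 4 of them, against a random median of 8 (1.96 percentile). The other counts of these kinds lay inside the central 95%, and none was corrected for their number.

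At regions called in both libraries, reads over the background floor had a median log2 ratio to 2iL of −0.27 at 48 h (6981 regions, 68.0% lower) and −0.54 at 96 h (4822 regions, 82.2% lower). By strength in 2iL, the medians were 0.08 at 48 h and −0.14 at 96 h in the weakest 20% and −0.57 and −0.95 in the strongest, a trend that regression to the mean and the choice of regions called in both libraries give by themselves, so no dependence on strength is read from it. Near formative genes the median at 48 h was 0.20 over 30 regions, above 10000 random sets of shared regions of like strength, whose central 95% ran from −0.51 to −0.02. Some of the 30 are neighbours near the same gene, such as 5 near Etv5, and these sets were not drawn as whole genes. At 96 h the formative median was −0.29 over 22 regions, inside the range of its own random sets. Near naive genes the medians were −0.34 and −0.82, each inside the range of its own random sets. The later regions near naive genes were mostly 2iL regions: 50 of 55 at 48 h (90.9%) and 43 of 48 at 96 h (89.6%), beyond the central 95% of equally strong later regions, but inside it with an overlap of at least 50% of both regions (97.1 and 70.3 percentiles). Also beyond it in the main setting were the core (98.1 percentile), signalling (98.8) and control (0.54) lists at 48 h and the energy metabolism list (98.7) at 96 h. Each of these came inside it in at least 2 settings, the core list at the 52.6 and the signalling list at the 84.3 percentile with the stricter overlap, the control list at the 20.5 with lists of equal length and the energy metabolism list at the 91.4 with the stricter overlap. Near formative genes 31 of 46 (67.4%) and 27 of 41 (65.9%) were 2iL regions, inside it. The strongest 96 h region not called in 2iL, inside Kndc1, lies 6499 bp from Utf1, and the tenth strongest, inside Aire, lies 3980 bp from Dnmt3l.

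Fewer regions were called at 48 h and 96 h than in 2iL, by 20.3% and 49.0%. Lower read depth than in 2iL is argued against, since the background floor was 1.60 times that of 2iL at 48 h and 1.16 times at 96 h, and 1.49 and 1.09 times per bp of the shortest region. Between 48 h and 96 h the floor fell from 8.09 to 5.84 reads, so lower depth may account for part of the drop between those times. Whether a single uniform loss of enrichment by 48 h was the whole cause cannot be decided. Without replicates, the share of strong regions that differs between libraries of the same condition is unknown. Of the strongest 5% of 2iL regions 12.4% were missing at 48 h, against 1.64% of the strongest 5% at 48 h missing at 96 h. Of the strongest 20% at 48 h 10.1% were missing from 2iL, against 1.497% of those at 96 h missing from 48 h. That second comparison is limited further, since the 48 h library had the highest background floor. Of the same 48 h regions, 11.6% were missing at 96 h. A selective change of ESRRB binding on withdrawal may account for part of the difference. These values cannot tell it from a difference between single libraries. Less ESRRB protein, a weaker antibody step in a library, and any other difference between single libraries were not tested and stay open, since each condition has 1 library.

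Regions of 2iL near formative and core genes were called at 48 h more often than equally strong 2iL regions. Neighbouring regions being kept together is argued against as the cause for the core list, at the 99.9 percentile of random gene lists drawn as whole genes. For the formative list it cannot be decided. Its share of 68.2% lay at the 97.9 percentile, just above the upper bound of 67.4%. These random lists were not matched on strength. Place relative to gene ends is argued against, since matching on strength and place gave the 98.4 (formative) and 99.9 (core) percentiles. With any 1 gene left out, the formative list did not go below the 97.1 percentile (without Zic5), which is inside the central 95%, and the core list did not go below the 99.8 (without Sall4). The formative result rests on the 50 kb window, with the 79.6 percentile at 10 kb, the core result comes inside the central 95% with lists of equal length (88.8), both do so under the stricter overlap (85.5 and 92.4), and 18 comparisons were made without correction. ESRRB may be retained at these genes as cells leave the naive state, which remains a hypothesis to be tested with replicates.

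Local background at chromosome 8 summits was 1.12 times the autosomal median in 2iL, 1.14 times at 48 h and 1.03 times at 96 h, and the other 18 autosomes ranged from 0.895 to 1.06 in 2iL and 48 h. At 96 h the other autosomes ranged from 0.917 to 1.08. Fewer chromosome 8 summits had a background at the floor at 96 h, 9.23% against 12.7% to 26.3% on the others. The ratios that follow were taken at 2iL regions that overlapped a single region at 48 h and a single region at 96 h. For 2iL, the ratio of 2iL to 96 h background was 1.23, within the 1.08 to 1.297 of the other autosomes. The sequence or mappability of chromosome 8 may account for that, but so may an extra copy in both libraries. The ratio cannot tell these apart. For 48 h the ratio to 96 h was 1.25, above the 1.12 to 1.21 of the others, but its bootstrap interval of 1.202 to 1.296 reaches into that range, so sequence and a difference between the libraries cannot be told apart. An extra copy of chromosome 8 in part of the cells was not tested, since the input libraries were not used here. Chromosome 8 held 5.59%, 5.85% and 6.61% of regions in 2iL, at 48 h and at 96 h.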
